A study of Danio rerio with 16 samples.

How the data were processed

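Total RNA of zebrafish embryos was measured in 16 libraries, 10 embryos per treatment group, extracted with TRIZOL and treated with DNase I per the labels. Embryos had received into the yolk at 2 dpf 1 nl of 5 mg/ml of fluorescent polystyrene beads in polyvinylpyrrolidone (particle), the vehicle alone (mock), or no injection (control), and were taken at 1 or 3 days post injection (dpi). The labels give a bead diameter of 700 nm, while the file headers of particle_1dpi C and particle_3dpi C read 70 nm, and the sources used here do not settle which holds for these 2 libraries. Control and particle groups hold biological replicates A, B and C at each time and mock groups A and B, as the titles give them. The header for particle_1dpi B names replicate A and the characteristics of control_1dpi C read replica 1, and the titles were followed in both cases. Per the submitters' processing notes reads were aligned with Bowtie2 to GRCz10, handled with SAMtools and normalised with DESeq, with no versions given. The read counter, the annotation release, the treatment of strand and the treatment of reads shared between genes are not given in the sources used here.

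The deposited columns hold whole-number read counts per gene, not estimated counts or expected counts from a model, so that rounding changed no value. Only the size factor at the foot of each table holds decimals, and that line and a blank line, 2 per file, were left out. The deposited size factors were checked against median-of-ratios factors computed from control and treated libraries of the same time. They matched in each of the 4 sets for the treated libraries and in both particle sets for the controls, and differed for controls by at most 0.0702 and 0.274 relative in the mock sets. The tables list 31388 genes on 26 chromosome names, of which 31383 carry a symbol and 19925 an Entrez identifier. Library totals ran from 8679739 to 19840148 counts. Chi-square values per degree of freedom between libraries of the same group ran from 6.02 to 98.4, so that no library repeats the counts of another of its group.

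Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and drawn with python 3.11.15 and matplotlib 3.10.9. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 23623 genes. TMM scaling and edgeR quasi-likelihood tests on the means of the 6 groups were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log-CPM values used a prior count of 2, and random steps a seed of 1. Particle, mock and control groups were compared within each time, control embryos between both times, and the change of each difference between times as an interaction.

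Gene lists were tested with camera with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over 35 lists. The lists were complement cascade, coagulation and fibrinolysis, acute phase proteins, inflammatory cytokines and chemokines, NF-kB, AP-1 and JAK-STAT early response, pattern recognition, neutrophil markers, macrophage markers, interferon response, lysosome and phagosome, erythroid genes, phototransduction, lens crystallins and lens genes, exocrine pancreas, liver secreted proteins, lipoprotein and yolk lipid genes, cholesterol biosynthesis, intestinal epithelium, aryl hydrocarbon receptor and drug metabolism, Nrf2 and oxidative stress, heat shock and chaperones, unfolded protein response and integrated stress response, hypoxia and glycolysis, circadian clock and light response, glucocorticoid response, skeletal muscle, cardiac muscle, cell cycle, p53 and apoptosis, wound repair and matrix remodelling, epidermis and keratins, cartilage and bone, neurons and glia, vascular endothelium, and ribosomal proteins. Of 1303 members 1195 matched by symbol, 56 through the Entrez identifier and 9 through the Ensembl identifier, 43 did not match, and 12 genes that share the symbol si were not matched by it. A list needed 5 tested members.

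Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM, groups that do not overlap and a proper symbol, up to 4 members with the smallest p of each list with a called member, the 5 genes with the smallest p where fewer than 6 pass, and c3a.1, c9, cfb, il1b, mpx, mpeg1.1 and cyp1a in every comparison of treatments. Control embryos at both times give 5 genes each way, interactions give the 5 smallest p, and genes were left out in order of p where more than about 30 were named. A further gene that the rule names is not reported here. Alternatives were RLE size factors, DESeq2, limma-voom, no filter, only the libraries of the same time or of the groups compared, a term for replicate, and each library left out in turn. A library left alone in its group was assumed to vary like the others. Chosen after seeing the data were a term for library series (C, whose headers read combined, against A and B), the A and B libraries alone, these without mock_3dpi A, the removal of each library's trend with gene length, and leaving out each library for the correlation between both times.

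Whether replicate letters pair across groups was checked through the correlation of deviations from group means. For particle and control at 1 dpi it was 0.57, 0.31 and 0.75 for the 3 letters, and there a term for replicate gave 1 called gene, npas4a at 2.41 (adjusted p = 0.00336). Recovery was tested on simulated counts with 100 genes changed at each size, run on 23396 to 23403 genes. For particle against mock edgeR recovered 16% of 2-fold and 72% of 4-fold changes at 1 dpi (23400 genes) and 9% and 69% at 3 dpi (23398 genes). For particle against control it recovered 22% and 72% at 1 dpi (23403 genes) and 17% and 73% at 3 dpi (23402 genes), and for mock against control at 3 dpi 12% and 64% (23396 genes), with 2 or 3 unchanged genes called. DESeq2 recovered between 22% and 40% at 2-fold and called between 22 and 39 unchanged genes. Of 40 simulated lists without an effect camera called 0 in each comparison and fry at most 4. These lists held random genes drawn independently, so they cannot show how the preset correlation performs on members that vary together.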

Results

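RNA from whole zebrafish embryos was counted in 16 libraries of 6 groups, with 3 biological replicates for non-injected control and for particle-injected embryos and 2 for mock-injected embryos, at 1 and at 3 days post injection (dpi). Each library held between 8679739 and 19840148 counted reads. The file headers give replicates A and B the same series name and call replicate C, present only for control and particle embryos, combined. C is treated here as another library series, a reading the headers do not state. The particles were red fluorescent polystyrene beads in polyvinylpyrrolidone, placed in the yolk at 2 days post fertilization (2 dpf). The labels give their diameter as 700 nm, but the file headers of 2 libraries, particle_1dpi C and particle_3dpi C, read 70 nm, so the bead size in these is uncertain. Values from the A and B libraries alone leave them out. Particle against mock separates the particles from the injection and its vehicle, particle against control takes in both, and mock against control shows injection and vehicle alone. Fold changes are given as log2 values, and levels as CPM, counts scaled to library size, with the SD over libraries.

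Between particle and mock embryos at 1 dpi the lowest p values belonged to EGR4 (ENSDARG00000077799, chromosome 23) and npas4a (ENSDARG00000055752, chromosome 14), transcription factor genes induced within minutes of neuronal activity. EGR4 stood at 9.14 ± 1.5 CPM with particles (n = 3) and 2.03 ± 0.428 with mock injection (n = 2), a log2 value of 2.17 (SE 0.31, adjusted p = 0.142). For npas4a the levels were 19.4 ± 3.63 and 5.08 ± 0.0523, a log2 value of 1.93 (SE 0.352, adjusted p = 0.924). The early response gene fosab (ENSDARG00000031683, chromosome 20) stood at 12.4 ± 0.0871 and 4.43 ± 0.089, a log2 value of 1.48. The lipid droplet coat gene plin2 (ENSDARG00000042332, chromosome 15) stood at 14.3 ± 2.68 and 3.19 ± 0.702, a log2 value of 2.17. Non-injected embryos of the same time held EGR4 at 3.97 ± 1.16 CPM and plin2 at 12.2 ± 8.14 (n = 3). The unnamed gene si:dkey-74i1.5 stood at 0.142 ± 0.0765 and 1.38 ± 0.389.

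None of these genes passed the test. Of 23623 genes edgeR called 0 between particle and mock at 1 dpi, with 538 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 4 higher and 0 lower, among them npas4a with adjusted p = 0.000748 and EGR4 with adjusted p = 3.98e-06. Within the A and B libraries alone npas4a had a log2 value of 2.08 (adjusted p = 0.00111), EGR4 2.17 (adjusted p = 0.0377) and fosab 1.49 (adjusted p = 0.0223). With a term for library series npas4a had 1.93 (adjusted p = 0.0261) and EGR4 2.07 (adjusted p = 0.143). Over every alternative the adjusted p of npas4a ran from 0.000748 to 1 and that of EGR4 from 3.98e-06 to 1.

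**Figure D1:**
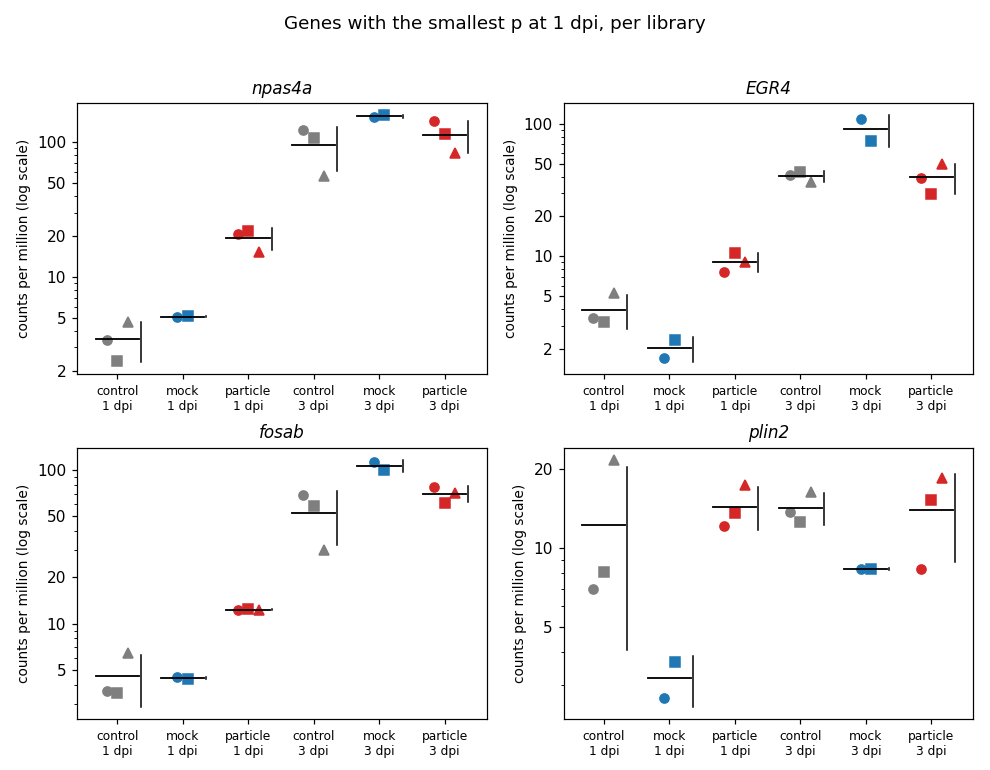
CPM of npas4a, EGR4, fosab and plin2 in every library, with the group mean and SD. Circles, squares and triangles are replicates A, B and C.

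Secreted products of the liver were lower with particles than with mock injection at 1 dpi, and lens genes were higher, by the camera test of lists with a preset correlation. None of these calls held when the correlation was estimated per list, the lowest value being adjusted p = 0.504 with an estimated correlation. The liver secreted proteins, which include albumin-like and transport proteins of plasma, fell by 1.11 on average, with 0 of 36 members above 0. Acute phase proteins had a mean of −1.04, coagulation and fibrinolysis −0.83 and the complement cascade, the plasma proteins that tag and lyse microbes, −0.65, with 5 of 33 members above 0. Macrophage markers had a mean of −0.49, and lens crystallins and lens genes stood higher by 0.79, with 53 of 57 members above 0. At this time lens genes were lower with mock injection than in controls. For particle against control the lens list did not pass the preset test, so this difference leans on the mock libraries. The lens list holds crygm2d genes, near-identical copies that may share reads, so its members are not all separate counts. No member of these lists passed on its own. In the complement list cfb stood at 2.47 ± 2.3 against 7.3 ± 0.746 CPM, c3a.1 at 6.58 ± 5.86 against 13.5 ± 3.26 and c9 at 6.62 ± 6.32 against 12.9 ± 3.93. The macrophage gene mpeg1.1 stood at 2.52 ± 0.41 against 4.01 ± 0.497. Log2 values were −0.83 for the cytokine gene il1b, −0.38 for mpx, the myeloperoxidase of neutrophils, and −0.52 for cyp1a, a detoxifying enzyme gene.

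Of 35 lists the preset test passed 3 upward and 17 downward between particle and mock at 1 dpi, and 0 with an estimated correlation. Without particle_1dpi C 13 lists passed. The call held without any single library for 11 lists, which besides those above were cholesterol biosynthesis (mean −0.34), intestinal epithelium (−0.69), skeletal muscle (−0.42), wound repair and matrix remodelling (−0.30) and epidermis and keratins (−0.37). Sizes leaned on single libraries. The liver list stood at −2.30 without particle_1dpi A and −0.64 without particle_1dpi C, the complement list at −1.17 without particle_1dpi A and −0.42 without mock_1dpi B. Without particle_1dpi A intestinal epithelium stood at −2.16, coagulation at −1.73, acute phase at −1.75, skeletal muscle at −0.64 and cholesterol at −0.54, and without particle_1dpi C at −0.27, −0.49, −0.68, −0.14 and −0.21. Wound repair stood at −0.10 without mock_1dpi A and −0.14 without particle_1dpi C, and epidermis at −0.24, −0.55 and −0.16 without mock_1dpi A, particle_1dpi B and particle_1dpi C. Within the A and B libraries the liver list stood at −0.64, complement at −0.43, acute phase at −0.71 and lens at 0.91. With a term for library series liver stood at −0.78, complement at −0.56 and lens at 0.83.

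The other lists past the preset test at 1 dpi, particle against mock, lost their call without particle_1dpi C. Pattern recognition went from −0.36 to −0.27, lysosome and phagosome from −0.19 to −0.10, and aryl hydrocarbon receptor and drug metabolism from −0.32 to −0.05. Nrf2 and oxidative stress went from −0.21 to −0.10, cartilage and bone from −0.20 to −0.09, cardiac muscle from −0.13 to 0.20, cell cycle from 0.25 to 0.03 and ribosomal proteins from 0.16 to 0.06. Exocrine pancreas stood at −0.41, and at 0.44 without mock_1dpi A and −0.04 without particle_1dpi B. Calls were also lost for pattern recognition (−0.27) and ribosomal proteins (0.06) without mock_1dpi A, for cardiac muscle (0.07) and cartilage (−0.14) without mock_1dpi B, and for cardiac muscle (0.07) without particle_1dpi B. Lists that did not pass were inflammatory cytokines and chemokines (mean −0.12), the NF-kB, AP-1 and JAK-STAT early response (0.04, with 3 of 35 members higher when adjusted over the list alone), neutrophil markers (−0.22), interferon response (0.11), erythroid genes (−0.02), phototransduction (−0.18) and lipoprotein and yolk lipid genes (−0.27). Nor did heat shock and chaperones (−0.11), the unfolded protein response and integrated stress response (0.03), hypoxia and glycolysis (−0.04), circadian clock and light response (0.01), glucocorticoid response (−0.06), p53 and apoptosis (0.04), neurons and glia (0.05) or vascular endothelium (−0.06).

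At 3 dpi the red cell genes slc4a1a and tfr1a, the carrier genes slc7a5 and slc2a1b and the kinase gene rps6ka5 were among those higher with particles than with mock injection, and mmp9 and ccl19b among those lower. The erythrocyte anion exchanger slc4a1a (ENSDARG00000012881, chromosome 3) rose from 5.14 ± 0.274 CPM in mock (n = 2) to 33 ± 4.09 in particle embryos (n = 3), a log2 value of 2.68 (SE 0.577, adjusted p = 0.021). The transferrin receptor tfr1a of erythroid precursors rose by 2.07 (adjusted p = 0.0174). The kinase gene rps6ka5 (ENSDARG00000060551, chromosome 17) rose by 2.37 (SE 0.372, adjusted p = 0.0106), from 1.72 ± 0.887 to 8.76 ± 0.305. The amino acid carrier slc7a5 rose by 2.37 (adjusted p = 0.0141) and the glucose carrier slc2a1b (ENSDARG00000007412, chromosome 6) by 2.18 (SE 0.366, adjusted p = 0.0123). The activin receptor gene acvr1bb rose by 2.60 (adjusted p = 0.0138), and ankrd52a by 2.41 (adjusted p = 0.0144). Further rises were 2.36 for pcdh20, a protocadherin gene (adjusted p = 0.0198), and 2.15 for casp6, an effector caspase gene (adjusted p = 0.0212). Non-injected embryos of 3 dpi (n = 3) held rps6ka5 at 9.11 ± 3.11 CPM, near the particle level. For slc2a1b they held 6.69 ± 0.932, against 7.12 ± 2.68 with particles and 1.56 ± 0.365 with mock injection. Control levels of slc4a1a (18.8 ± 4.5) and acvr1bb (8.37 ± 2.1) lay between those of mock and particle embryos. Between particle and control edgeR called 0 genes at this time, so these rises are relative to mock only.

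Among lower genes at 3 dpi, mmp9 (ENSDARG00000042816, chromosome 8), a gelatinase of injured tissue, fell from 53.8 ± 28 CPM with mock injection to 10.4 ± 6.29 with particles, a log2 value of −2.36 (SE 0.505, adjusted p = 0.0202). Non-injected embryos of 3 dpi held mmp9 at 7.49 ± 4.58 CPM (n = 3), near the particle level. The chemokine gene ccl19b had −3.32 (adjusted p = 0.0259), and stood at −0.91 (adjusted p = 0.428) without mock_3dpi B, the library that held most of its reads. The fatty acid binding protein gene fabp1a had −1.56 (adjusted p = 0.0155), and −0.94 (adjusted p = 0.272) without mock_3dpi A. Further falls were −1.65 for lrrcc1 (adjusted p = 0.0142), −1.53 for snap23.2, a vesicle fusion gene (adjusted p = 0.0441), and −0.78 for the ferritin gene fth1b (adjusted p = 0.0174). The linker histone gene histh1l had −1.64 (adjusted p = 0.0123), an uncertain value since its reads may be shared with close copies. The cytokine gene il1b had −1.78 (adjusted p = 0.0898), mpeg1.1 1.25 (adjusted p = 0.105), c3a.1 1.63 (adjusted p = 0.183), c9 1.28, cfb 1.29, cyp1a 0.97 and mpx 0.42, none of which passed.

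**Figure D2:**
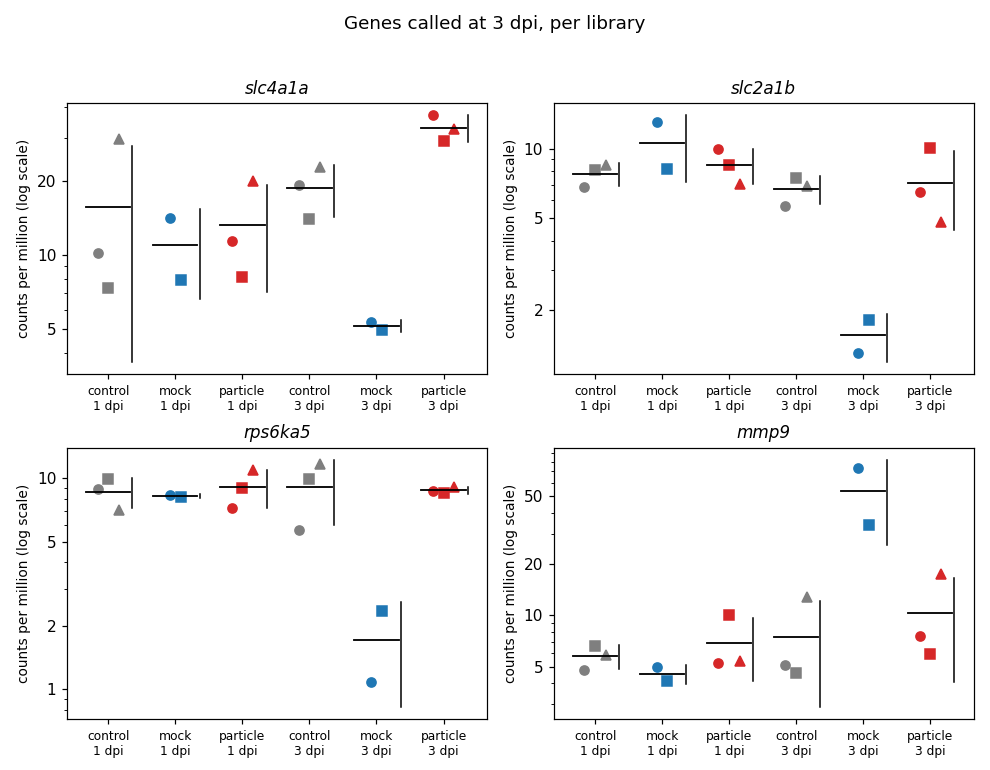
CPM of slc4a1a, slc2a1b, rps6ka5 and mmp9 in every library, with the group mean and SD. Circles, squares and triangles are replicates A, B and C.

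As groups at 3 dpi, erythroid genes were higher with particles than with mock injection and ribosomal protein genes, which build the translation machinery, were lower, by camera with a preset correlation. Neither call held with an estimated correlation, where both lists had adjusted p = 0.941, or with fry. By the preset test both held without any single library. All 23 erythroid genes had log2 values above 0, with a mean of 1.26 (SD 0.77), 4 passed on their own and 6 when adjusted over the list alone. Globin genes in this list may share reads with close copies, so its members are not all separate counts. Of 72 ribosomal protein genes 25 fell on their own and 70 when adjusted over the list alone, with a mean of −0.89 (SD 0.11). Skeletal muscle genes had a mean of −0.45. In lysosome and phagosome 4 of 33 genes rose, among them the lysosomal enzyme gusb (1.43, adjusted p = 0.0132) and the lysosomal receptor scarb2 (1.21, adjusted p = 0.014). In cartilage and bone 3 of 34 rose, among them the collagen gene col9a1a (1.58, adjusted p = 0.0152). In the clock list per3, a repressor of the circadian loop, rose by 1.63 (adjusted p = 0.0149). In neurons and glia 2 rose and 2 fell, with the glutamate carrier slc17a6b at 1.62 (adjusted p = 0.0151).

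In the whole set edgeR called 1249 genes higher and 803 lower between particle and mock at 3 dpi, DESeq2 1809 and 1481, and limma-voom 856 and 599. With only the libraries of 3 dpi edgeR called 8 genes, and with only both groups compared it called 0, with 5196 at an unadjusted p under 0.05. Camera with a preset correlation passed 3 lists, erythroid, ribosomal and skeletal muscle, each with adjusted p = 0.941 with an estimated correlation. By the preset test 10 lists passed without mock_3dpi A, 10 without particle_3dpi C, 8 without particle_3dpi A and 5 without mock_3dpi B. The mock_3dpi A library stood apart from the rest, with 38.8% of its counts in its 100 most abundant genes against 19.9% to 32.0% elsewhere, a TMM factor of 0.694, and high ribosomal protein genes. Both mock libraries of 3 dpi had the fewest detected genes (25741 and 25785, others from 26158), the highest mitochondrial share (5.48% and 6.13%, others up to 5.02%) and the lowest TMM factors (0.886 for mock_3dpi B, others from 0.937). Without mock_3dpi A 2 genes were called, slc4a1a had 2.73 (adjusted p = 0.221), rps6ka5 1.90 (adjusted p = 0.154), slc2a1b 1.95 (adjusted p = 0.17), mmp9 −1.70 (adjusted p = 0.272) and acvr1bb 1.81 (adjusted p = 0.162). Without mock_3dpi B acvr1bb had 4.18 and ankrd52a 3.68. Without mock_3dpi A the list means were 1.61 for erythroid, −0.35 for ribosomal and −0.12 for skeletal muscle, which lost its call. Genes called numbered 3911 without mock_3dpi B, 317 without particle_3dpi A, 64 without particle_3dpi B, and 2217 without particle_3dpi C.

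Within the A and B libraries 5679 genes were called at 3 dpi between particle and mock, 2012 of them shared with the pooled call, and a term for library series gave 5835. In the A and B libraries slc4a1a had 2.69 (adjusted p = 0.00237), rps6ka5 2.35 (adjusted p = 0.0034) and mmp9 −2.98 (adjusted p = 0.00293). With mock_3dpi A left out of the A and B libraries as well, an alternative chosen after the values were seen, 1407 genes were higher and 1071 lower. In the A and B libraries the list means were 1.18 for erythroid and −0.96 for ribosomal proteins. There 10 lists passed that had not passed with all libraries, such as liver secreted proteins (1.64, against 1.21 with all) and the complement cascade (0.88, against 0.64 with all). Log2 values of all 23623 genes at 1 and 3 dpi had a correlation of −0.22 for particle against mock (Spearman −0.32). With 0 genes called at 1 dpi, none could be called at both times.

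The change of the particle and mock difference from 1 to 3 dpi was tested as an interaction. At 3 dpi EGR4 stood at 39.5 ± 10.1 CPM with particles (n = 3), 91.5 ± 25 with mock injection (n = 2) and 40.2 ± 3.56 without injection (n = 3). The mock libraries thus stood apart from both other groups, and the order of particle and mock was the reverse of that at 1 dpi. In this interaction EGR4 passed with −3.38 (SE 0.398, adjusted p = 0.0152). Its adjusted p was 0.214 without mock_1dpi A, 0.159 without mock_1dpi B, 0.0599 without particle_1dpi B, 0.124 without mock_3dpi A, 0.067 without particle_3dpi A, and 0.0038 in the A and B libraries. No other gene passed, and 5656 stood at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 1719. The genes kras and mlec had 2.16 and 2.62, both with adjusted p = 0.0524. Without mock_3dpi B 2735 genes were called, 679 without particle_3dpi C, and 2587 in the A and B libraries.

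Against non-injected control embryos at 1 dpi, the activity-induced gene npas4a rose from 3.48 ± 1.13 CPM (n = 3) to 19.4 ± 3.63 in particle embryos (n = 3), a log2 value of 2.44 (SE 0.313, adjusted p = 0.0431). It was the only gene called of 23623, with 517 at an unadjusted p under 0.05, 7 called by DESeq2 and 0 by limma-voom. The call was lost without any 1 of the 6 libraries, with log2 values from 2.25 to 2.72, at adjusted p = 0.271 without control_1dpi A, 0.412 without control_1dpi B, and 0.0951 without control_1dpi C. It stood at adjusted p = 0.221 without particle_1dpi A, 0.265 without particle_1dpi B and 0.0504 without particle_1dpi C. In the A and B libraries npas4a had 2.87 (adjusted p = 7.87e-05), and with a term for library series 2.41 (adjusted p = 0.000366), and over every alternative its adjusted p ran from 9.39e-10 to 1. At 3 dpi npas4a stood at 114 ± 30.2 CPM with particles and 95.6 ± 34.8 without injection (n = 3 each), and the mock libraries held 154 and 159. The difference of particle and control in npas4a changed by −2.19 (SE 0.414) between times, not called with all libraries. For this change the adjusted p was 0.0023 in the A and B libraries and 0.0123 with DESeq2. Other genes did not pass at 1 dpi. The gene fosab stood at 12.4 ± 0.0871 against 4.55 ± 1.68 CPM (1.41, adjusted p = 0.81) and the phagocyte gene CD68 at 23.8 ± 5.64 against 9.08 ± 3.68 (1.39). The neuropeptide precursor VGF stood at 17.8 ± 2.6 against 9.75 ± 0.835 (0.86), and si:dkey-221j11.3 had 1.39. Log2 values were 2.44 for c9, 1.87 for cfb, 0.90 for c3a.1, 0.85 for mpx, 0.15 for mpeg1.1, 0.12 for cyp1a and 0.10 for il1b.

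Liver and immune groups were higher in particle than in control embryos at 1 dpi by the preset test. No list passed with the correlation estimated per list, the lowest being adjusted p = 0.145 with an estimated correlation. Liver secreted proteins rose by 1.86 on average (33 of 36 members above 0), acute phase proteins by 1.27, lipoprotein and yolk lipid genes, which carry yolk fat into the body, by 1.03, and the complement cascade by 0.79 (27 of 33). Smaller rises were seen for inflammatory cytokines and chemokines (0.49), neutrophil markers (0.41), the NF-kB, AP-1 and JAK-STAT early response (0.36, with 3 members higher when adjusted over the list alone) and p53 and apoptosis (0.18). The preset test passed 18 lists upward and 3 downward at 1 dpi. The lists named here kept their calls without any single library, but without particle_1dpi A liver stood at 0.66, acute phase at 0.56, lipoprotein at 0.42 and complement at 0.27. Without control_1dpi A acute phase stood at 2.00 and neutrophil markers at 0.67, and without particle_1dpi B neutrophil markers stood at 0.17. Within the A and B libraries liver stood at 2.04, complement at 1.06, cytokines at 0.25 and the early response at 0.35. With a term for library series liver stood at 1.63 and complement at 0.71.

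Other lists past the preset test, particle against control at 1 dpi, lost their call without a single library. Without particle_1dpi A coagulation and fibrinolysis went from 1.1 to 0.20, exocrine pancreas from 1.33 to −0.97, intestinal epithelium from 1.26 to −0.22 and aryl hydrocarbon receptor and drug metabolism from 0.55 to −0.04. Glucocorticoid response went from 0.35 to 0.14, skeletal muscle from 0.26 to 0.05, cardiac muscle from 1.14 to 0.23 and vascular endothelium from 0.25 to 0.06 without the same library. Without control_1dpi C erythroid genes went from −0.44 to 0.09, wound repair and matrix remodelling from 0.32 to 0.15, cartilage and bone from 0.28 to 0.13 and ribosomal proteins from −0.19 to 0.11. Exocrine pancreas (1.17), intestinal epithelium (0.89), glucocorticoid response (0.15) and skeletal muscle (−0.01) also lost their calls without control_1dpi C, and skeletal muscle (0.13) without particle_1dpi B. The neurons and glia list went from −0.11 to −0.06, −0.03 and −0.12 without control_1dpi A, control_1dpi B and particle_1dpi C.

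At 3 dpi the gene groups of the liver and of red cells were higher with particles than in non-injected embryos by the preset test, while no single gene was called. With the correlation estimated per list 0 lists passed, the lowest being adjusted p = 0.314 with an estimated correlation. Liver secreted proteins rose by 1.59 on average (SD 0.78, 32 of 36 members above 0), acute phase proteins by 1.15, coagulation and fibrinolysis by 1.04, the complement cascade by 1.01 (SD 0.96, 27 of 33), erythroid genes by 0.41 (23 of 23) and epidermis and keratins by 0.24. Members of the complement list stood at 32.7 ± 21.6 against 5.95 ± 2.54 CPM for c9 (2.45), 10.2 ± 5.18 against 2.05 ± 1.23 for cfb (2.3) and 9.71 ± 4.16 against 3.69 ± 0.684 for c3a.6 (1.39), with n = 3 in both groups. With c3a.1 at 2.22, none of these passed. The fetuin gene ahsg2 had 2.63 (SE 0.673) and the uridine phosphorylase gene upp2 5.04 (SE 1.14), both with adjusted p = 1. The genes BX276122.1 and si:ch211-161h7.5 had 1.27 and 0.99, and mpx had 0.84, il1b 0.83, cyp1a 0.86 and mpeg1.1 0.46.

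For particle against control at 3 dpi edgeR called 0 genes, with 363 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well. The preset camera test passed 21 lists upward and 5 downward, and in all 17 without control_3dpi A, 17 without control_3dpi C and 14 without particle_3dpi A. The 6 lists named as risen kept their calls without any single library. Without particle_3dpi A liver stood at 0.81, coagulation at 0.46 and complement at 0.59, and without control_3dpi B liver stood at 2.56 and coagulation at 1.6. Epidermis and keratins stood at 0.15, 0.16 and 0.40 without particle_3dpi B, control_3dpi A and control_3dpi C. In the A and B libraries complement stood at 1.31, liver at 1.64 and erythroid genes at 0.50, and with a term for library series complement at 0.92. The change from 1 to 3 dpi was 0.22 for complement and −0.27 for liver, neither past the test, and 0.85 for erythroid genes (adjusted p = 0.315 with an estimated correlation).

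The other lists past the preset test for particle against control at 3 dpi lost their call when 1 library was left out, many of them under more than 1 library and some with little change of the mean. Without control_3dpi C the early response went from 0.30 to 0.25, the lens list from 0.20 to −0.09, exocrine pancreas from 1.15 to 0.66, lipoprotein and yolk lipid genes from 0.52 to 0.34 and intestinal epithelium from 0.62 to 0.31. The same library took aryl hydrocarbon receptor and drug metabolism from 0.32 to 0.15, heat shock and chaperones from −0.08 to 0.08, glucocorticoid response from 0.29 to 0.17, cardiac muscle from 0.41 to 0.28 and p53 and apoptosis from 0.12 to 0.06, each with its call lost. Without control_3dpi A the calls were lost for inflammatory cytokines and chemokines (0.26 to 0.25), neutrophil markers (0.43 to 0.28), macrophage markers (0.32 to 0.24) and wound repair and matrix remodelling (0.19 to 0.13). The same held for cartilage and bone (0.21 to 0.09), neurons and glia (−0.08 to −0.06), ribosomal proteins (−0.10 to −0.07) and cholesterol biosynthesis (−0.10 to 0.03). Without particle_3dpi A the cell cycle list went from −0.22 to −0.03 and lysosome and phagosome from 0.12 to 0.04. Without particle_3dpi A calls were also lost for macrophage markers (0.17), lens (−0.17), exocrine pancreas (−0.76), cholesterol (−0.02), drug metabolism (0.14), heat shock (0.02), glucocorticoid response (−0.02), cardiac muscle (0.15), p53 (0.05), wound repair (0.11) and neurons (−0.04). Without particle_3dpi B they were lost for p53 (0.11), cartilage (0.11), cardiac muscle (0.39) and ribosomal proteins (−0.05), and without particle_3dpi C for cytokines (0.03), neutrophil markers (0.29) and cholesterol (−0.11). Without control_3dpi B cytokines (0.18), cholesterol (−0.01) and ribosomal proteins (−0.03) lost theirs, and without control_3dpi A cardiac muscle (0.30), while lysosome and phagosome lost its call at 0.12 without control_3dpi C.

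**Figure D3:**
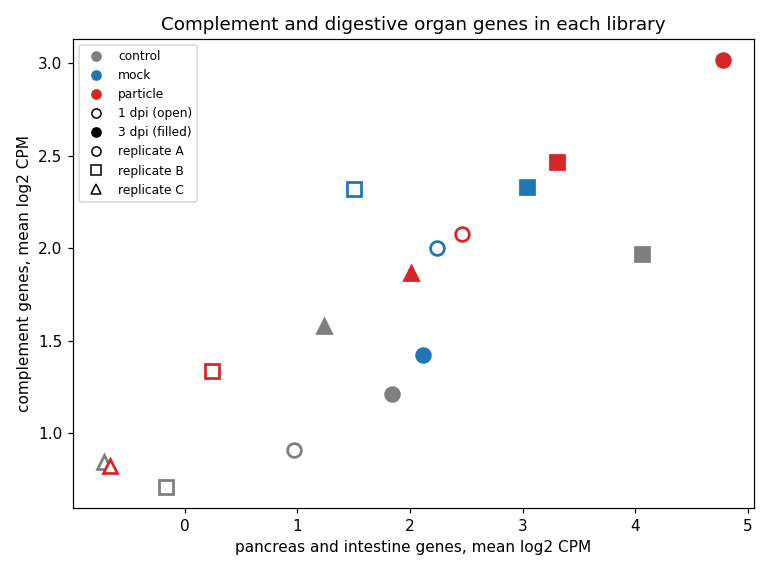
Mean log2 CPM of complement genes against that of pancreas and intestine genes in each library. Open symbols are 1 dpi and filled symbols 3 dpi.

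After mock injection, plasma protein genes of the liver and genes of the gut were higher at 1 dpi than in non-injected embryos by the preset test, and lens genes were lower. Again 0 lists passed with the correlation estimated per list, the lowest being adjusted p = 0.247 with an estimated correlation. Liver secreted proteins rose by 2.97 on average, with 34 of 36 members above 0 and 24 higher when adjusted over the list alone, acute phase proteins by 2.31 (10), coagulation and fibrinolysis by 1.94 (12), and the complement cascade by 1.44 (11). Lens genes fell by 0.80 (2 of 57 above 0, close copies included). Myeloid groups rose as well, macrophage markers by 0.58, neutrophil markers by 0.63, pattern recognition by 0.51 and inflammatory cytokines and chemokines by 0.61, the last at 0.06 without mock_1dpi A. By gene, VGF stood at 22.3 ± 0.942 CPM (n = 2) against 9.75 ± 0.835 (n = 3), a log2 value of 1.2 (SE 0.187, adjusted p = 0.37), and CD68 at 26.8 ± 2.35 against 9.08 ± 3.68 (1.57, adjusted p = 0.438). The phagocyte protease ctssb.2 stood at 5.86 ± 0.206 against 1.1 ± 0.662 (2.47) and ptgs2a, a prostaglandin synthase, at 12.9 ± 4.67 against 5.91 ± 0.349 (1.13). Complement genes c9 (3.41, SE 0.996), cfb (3.44) and c3a.1 (1.94) did not pass, nor did rnaseka (0.93), mpx (1.23), mpeg1.1 (0.82), il1b (0.93) or cyp1a (0.64).

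Across the mock and control embryos of 1 dpi edgeR called 0 genes, with 2669 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 51 higher and 4 lower. Camera with a preset correlation passed 24 lists upward and 4 downward. Besides those above, lists that kept the call without any single library were lipoprotein and yolk lipid genes (1.3), intestinal epithelium (1.94), exocrine pancreas (1.74), lysosome and phagosome (0.30), aryl hydrocarbon receptor and drug metabolism (0.87) and Nrf2 and oxidative stress (0.35). Skeletal muscle (0.69), cardiac muscle (1.28), wound repair and matrix remodelling (0.61), epidermis and keratins (0.49), cartilage and bone (0.48) and vascular endothelium (0.31) kept it as well. Exocrine pancreas stood at 2.88 without control_1dpi A and 0.89 without mock_1dpi A, and without control_1dpi C macrophage markers stood at 0.37 and skeletal muscle at 0.41. Calls lost without a library were those of phototransduction (0.21, and −0.19 without control_1dpi C), cell cycle (−0.27, and 0.07 without control_1dpi C), ribosomal proteins (−0.35, and −0.05 without control_1dpi C) and glucocorticoid response (0.42, and 0.21 without control_1dpi C). Without mock_1dpi A calls were lost for the early response (0.32 to 0.20), phototransduction (0.08), neurons and glia (−0.16 to −0.15) and heat shock and chaperones (mean 0.23 with a median of −0.01, to 0.11). Without control_1dpi A and control_1dpi B neurons (−0.12 and −0.08) and heat shock (0.26 and 0.22) lost theirs. Within the A and B libraries liver stood at 2.68, complement at 1.5 and lens at −0.77.

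At 3 dpi mock-injected embryos held more transcripts of mmp9 and fewer of rps6ka5 and of the carriers slc7a5, slc2a1b and slc1a6 than non-injected embryos. The gelatinase gene mmp9 rose from 7.49 ± 4.58 CPM (n = 3) to 53.8 ± 28 (n = 2), a log2 value of 2.81 (SE 0.514, adjusted p = 0.0336), and nsa2, a ribosome biogenesis gene, by 2.02 (adjusted p = 0.0341). Further rises were 1.62 for cbx7a, a Polycomb gene (adjusted p = 0.0428), 1.4 for fabp1a (adjusted p = 0.0438) and 1.37 for the stress gene NUPR1L (adjusted p = 0.0311). Smaller ones were 1.00 for casp9 (adjusted p = 0.0442), 0.86 for the cryptochrome gene cry1bb (adjusted p = 0.0311), 0.75 for fth1b (adjusted p = 0.0438) and 1.52 for histh1l, whose reads may be shared with close copies. Falls were seen for rps6ka5 at −2.43 (SE 0.373, adjusted p = 0.0311), slc7a5 at −2.20 (adjusted p = 0.0403), slc2a1b at −2.10 (SE 0.366, adjusted p = 0.0312), and the glutamate carrier slc1a6 at −2.13 (adjusted p = 0.0372). The aryl hydrocarbon receptor repressor ahrrb fell by 2.16 (adjusted p = 0.0432), acvr1bb by 2.09, mri1 by 2.15, per3 by 1.43, scarb2 by 1.12 and gusb by 1.1. Without mock_3dpi A nsa2 had 1.25, fabp1a 0.76, NUPR1L 0.75, per3 −0.91, mri1 −1.32 and acvr1bb −1.30, none of them called. Without mock_3dpi B slc7a5 had −3.37, per3 −2.21, mri1 −4.0 and acvr1bb −3.67. Values that did not pass were 2.60 for il1b (8.41 ± 9.28 against 1.34 ± 0.263 CPM, adjusted p = 0.0589), −1.33 for slc17a6b, −0.84 for neu1, 1.16 for c9, 1.00 for cfb, 0.59 for c3a.1, 0.43 for mpx, −0.79 for mpeg1.1 and −0.11 for cyp1a.

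Ribosomal proteins rose by 0.78 on average between mock and control at 3 dpi (all 72 members above 0, 67 higher when adjusted over the list alone, A and B libraries 0.67), and this was the only list of 8 past the preset test whose call held without any single library. The ribosomal list had adjusted p = 0.954 with an estimated correlation, and 0 lists passed that way, the lowest being adjusted p = 0.700 with an estimated correlation. By the preset test 16 lists passed without mock_3dpi A, 13 without control_3dpi B and 3 without mock_3dpi B. The other means were 0.85 for inflammatory cytokines and chemokines (0.49), 0.47 for the early response (0.06), −0.85 for erythroid genes (−0.78), −0.58 for cholesterol biosynthesis (−0.64) and 0.38 for glucocorticoid response (0.25), with the value without mock_3dpi B, where each call was lost, in parentheses. Means were 0.41 for lens genes (−0.18 without mock_3dpi A, 0.13 without control_3dpi C) and 0.46 for skeletal muscle (0.13 without mock_3dpi A). Cholesterol (−0.46) and glucocorticoid response (0.34) lost their calls without control_3dpi A too, and glucocorticoid response (0.26) without control_3dpi C. Genes called by edgeR were 103 higher and 283 lower between mock and control at 3 dpi, with 0 called by limma-voom and 655 and 1038 by DESeq2. With only the libraries of 3 dpi edgeR called 0 (4784 at an unadjusted p under 0.05), and 0 with only both groups compared (4144). Without mock_3dpi A, the library that stood apart, 0 genes were called, mmp9 had 2.15 (adjusted p = 0.358), rps6ka5 −1.96 (adjusted p = 0.279) and the ribosomal list 0.24. Genes called numbered 2870 without mock_3dpi B, 0 without control_3dpi B, 0 without control_3dpi C, 127 without control_3dpi A, 615 in the A and B libraries and 3031 with a term for library series.

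Of the 283 genes lower with mock injection than in control embryos at 3 dpi, 281 were among those higher with particles than with mock injection (14.96 expected without any link), and 96 of the 103 higher genes were among those lower with particles (3.5 expected). The log2 values of both comparisons had r = −0.89 and a covariance of −0.396, where simulated data without any effect gave −0.63 and −0.130 because both use the same mock libraries. Part of the excess may come from these shared libraries, and with 2 mock libraries they were not split. At 1 dpi both comparisons had r = −0.85 and a covariance of −0.233, where the simulated data gave −0.60 and −0.114. The changes from 1 to 3 dpi in mock against control included 0 called genes, with 5508 at an unadjusted p under 0.05 and 1525 called by DESeq2. There were 17 lists past the preset test (7 without mock_3dpi B), among them liver secreted proteins at −2.59, complement at −1.07 and ribosomal proteins at 1.13 (lowest adjusted p = 0.661 with an estimated correlation).

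**Figure D4:**
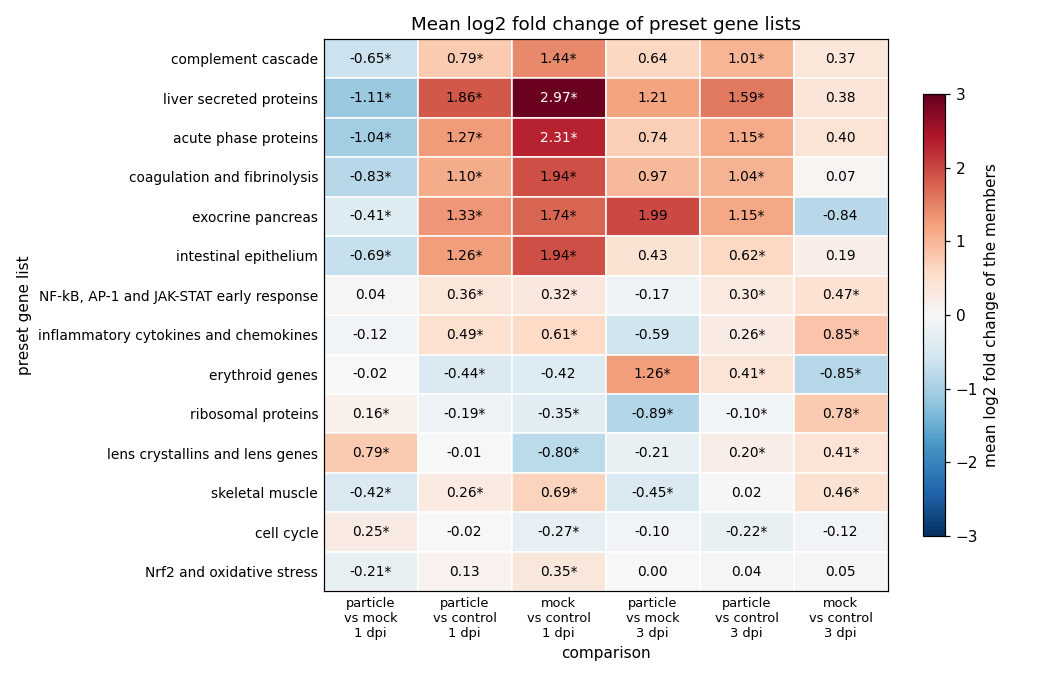
Mean log2 fold change of 14 gene lists in the 6 comparisons between treatments at 1 and 3 dpi. An asterisk marks lists past the preset camera test.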

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

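Chosen after the result was seen were the tests on mock_3dpi A, the tests on npas4a and EGR4, those of library series on the complement list and the comparison of splits by letter pairs. The removal of the trend with gene length was chosen after seeing the data but before its own result.

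A test of the difference between both times marked EGR4, whose particle against mock value changed by −3.38 from 1 to 3 dpi (adjusted p = 0.0152). Over the other settings its adjusted p ran from 1.69e-10 with DESeq2 to 0.214 without mock_1dpi A, with 0.0691 by limma-voom. Tests of the same kind marked 17 lists for particle against mock, 6 for particle against control and 17 for mock against control, all with the preset correlation and 0 with an estimated one. Without mock_3dpi B these counts were 8 for particle against mock and 7 for mock against control. For particle against control they ran from 5 without control_3dpi A to 14 without particle_1dpi C, of which 4 were among the 6 in the same direction. There 10 lists passed without control_1dpi A, 12 without particle_1dpi A, control_3dpi B, particle_3dpi A or particle_3dpi C, and 13 without control_3dpi C. In particle against control the 6 were erythroid genes (0.85), lens (0.21), heat shock and chaperones (−0.20), skeletal muscle (−0.25), cardiac muscle (−0.73) and cell cycle (−0.20).

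In the first pattern, genes higher with particles than with mock injection at 3 dpi were those lower with mock injection than in controls. If mock_3dpi A alone were the cause, mock_3dpi B would lie on either side of the controls. For genes tested with all libraries and called without mock_3dpi B, this library lay on the side of mock_3dpi A in 89.3%. Single controls lay there in 30.1% to 76.6%. The calls lean on mock_3dpi A, with 2 genes called without it (2478 within the A and B libraries), and the median shift of mock_3dpi B was 29.8% of that of mock_3dpi A on these genes, whose selection by mock_3dpi A inflates its own shift. Fold change rose with gene length (Spearman 0.223), but removing each library's trend with length left 2071 calls against 1988 among 19964 genes with a length, which argues against that trend as the whole cause. Particle embryos received the vehicle too, so its effect alone would move both groups away from the controls together. The log2 values of both against control at 3 dpi had r = −0.0108. Simulated data without any effect gave 0.436, from the shared controls. With edgeR 0 genes were called between particle and control. These values argue against an effect of the vehicle common to particle and mock embryos. No test here separates an effect of the vehicle that is absent with particles from a fault of both mock libraries. Both stay open, and these libraries had the fewest detected genes and the highest mitochondrial share.

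In the second pattern npas4a and EGR4 stood higher with particles than with mock injection at 1 dpi. A difference between library series is argued against, since the smaller of both values within the A and B libraries was 2.08. A later stage of development would move other genes of the control time course along, but the median ratio to that change over 301 genes was −0.0513 (upper quartile 0.0759), against 0.406 for npas4a. Time of day or light at sampling could move clock genes along, and their median ratio over 18 genes was −0.0368 (upper quartile 0.101). The clock gene per1a went the way this predicts, at 6.24 ± 0.932 CPM with particles against 3.69 ± 0.528 with mock injection, a log2 value of 0.76 (adjusted p = 0.924). The control change used for these ratios also holds development, so they cannot decide on time of day or light, which stays open. An activity response of neurons to particles is only a hypothesis found on these same data, and no test here addressed it. Handling just before freezing was not tested either.

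In the third pattern complement and liver lists stood higher with particles than in controls at both times. Particle and control groups hold replicates A, B and C alike, so a library series difference common to both cancels here whatever its size. Within the A and B libraries the complement list stood at 1.06 at 1 dpi and 1.31 at 3 dpi, so the rise did not rest on the C libraries. The share of digestive organs stays open: across 16 libraries, centred by group, complement and digestive scores had r = 0.82 (permutation p = 0.00588), and with the digestive score as a covariate complement genes outside the liver list went from 0.592 (SE 0.386) to 0.39 (SE 0.237) at 1 dpi and from 0.864 (SE 0.386) to 0.56 (SE 0.243) at 3 dpi. A response to injection and a different share or stage of liver and gut may both contribute. Mock embryos at 1 dpi showed the same groups higher, so that the particles themselves are not singled out at that time. At 3 dpi neither list passed the preset test for mock against control, or for particle against mock with all libraries. Within the A and B libraries both passed it, higher with particles than with mock injection. With the doubt on both mock libraries of 3 dpi, an effect of the particles at that time stays open.

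With 10 splits of 6 libraries a share under 0.05 was out of reach. Particle against control at 1 dpi gave 1 gene and 21 lists, as large in 2 and 3 of the splits, and the highest other split gave 949 genes and 23 lists. That split, control_1dpi A with particle_1dpi A and B against control_1dpi B and C with particle_1dpi C, points to a structure of the samples that crosses the treatments. These splits ignore that letters pair here, where a term for replicate block gave 1 gene as well. Of the 4 splits that part all 3 letter pairs, the real one gave 1 gene and 21 lists and the highest other 0 genes and 20 lists, while the split with 949 genes keeps the letters A and C together. Particle against control at 3 dpi gave 26 lists (as large in 2, highest other 26). Control embryos between both times gave 321 genes (as large in 1, highest other 0) and 22 lists (as large in 2, highest other 26). For the change of particle against control between times 50 of 50 splits gave as many as the 6 real lists (highest other 24), so that chance is not excluded for these. Where the real count was 0 genes every split reaches it, so the 10 of 10 splits for particle against control at 3 dpi (highest other 1) and the 50 of 50 for its change between times (highest other 111) decide nothing.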

How the results depend on the processing

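Settings chosen after seeing the data were the removal of trends with gene length, the library series term, the A and B libraries alone, and these without mock_3dpi A, besides the left-out libraries for the correlation between times. Over all settings 1647 values of named genes stayed on the same side of the threshold, 335 were weaker and 106 stronger. Direction was compared only where the main test or the setting called the gene. Values called in neither counted as the same whatever their sign. Of the list values 1751 were the same, 184 weaker and 32 reversed. Of the counts and correlations 127 stayed within the bound and 88 moved, and the cause was not tested except where fewer libraries were fitted. RLE scaling moved no count beyond 1.5 times, and no scaling moved the median of all genes by 0.1. Depth was not varied. In simulated data edgeR recovered 9% to 22% of 2-fold and 64% to 73% of 4-fold changes, so that many smaller changes would be missed in every comparison simulated.

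With DESeq2 genes called were 4, 3290 for particle against mock at 1 and 3 dpi, 7 for particle against control at 1 dpi, 55 and 1693 for mock against control at 1 and 3 dpi, 1719, 1 and 1525 for the changes between times of particle against mock, particle against control and mock against control, and 1300 for control embryos between times. With limma-voom 0 genes were called for particle against control at 1 dpi, mock against control at 3 dpi and the change of particle against mock. With an estimated correlation 0 lists passed over the 6 comparisons of treatments, against 106, and with fry 0.

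With only the libraries of the same time genes called were 8 for particle against mock at 3 dpi, 0 for particle against control at 1 dpi and 0 for mock against control at 3 dpi. With only the groups compared they were 0, 0 and 0 in the same order, 6 for mock against control at 1 dpi and 24 for control embryos, where fewer libraries estimate the spread, and the correlation of both times was −0.319. Without a filter that correlation was −0.0775 and among genes of at least 5 CPM −0.352.

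With a term for replicate block genes called were 5709 for particle against mock at 3 dpi, 9 and 2939 for mock against control at 1 and 3 dpi, 2513 and 2151 for the changes of particle against mock and mock against control, and 606 for control embryos. Letters were a weak guide to pairs, since 7 of 14 pairs of the same letter had a correlation under 0.1 and 8 libraries were closest to their own letter in every other group. Reversed lists were cell cycle (−0.0113) and ribosomal proteins (−0.0127) for particle against mock at 1 dpi, phototransduction (0.0184) and cell cycle (0.0255) for mock against control at 1 dpi, and lens (0.403) for control embryos.

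With the library series as a term genes called were 1 and 5835 for particle against mock, 9 for particle against control at 1 dpi, 3031 for mock against control at 3 dpi, 2539, 1 and 2070 for the 3 changes between times, and 1091 for control embryos. Reversed were cell cycle (−0.0110) and ribosomal proteins (−0.0150) for particle against mock at 1 dpi and phototransduction (0.0214) and cell cycle (0.0255) for mock against control at 1 dpi.

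With the A and B libraries alone genes called were 3 and 5679 for particle against mock, 2 for particle against control at 1 dpi, 615 for mock against control at 3 dpi, 2587, 1 and 352 for the 3 changes between times, and 657 for control embryos. Reversed were phototransduction (−0.180) and cell cycle (0.0730) for mock against control at 1 dpi and lens (0.161) for control embryos. Without mock_3dpi A as well the counts were 5 for particle against mock at 1 dpi, 7 and 6 for particle against control at 1 and 3 dpi, 9 and 99 for mock against control, 1768, 4 and 196 for the changes, and 1665 for control embryos. There ribosomal proteins stood at 0.0171 for particle against control at 1 dpi, phototransduction at −0.183 and cell cycle at 0.0685 for mock against control at 1 dpi, lens at −0.474 for mock against control at 3 dpi and lens at 0.150 for control embryos.

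Leaving out each library in turn gave 2 to 3911 genes for particle against mock at 3 dpi, 0 for particle against control at 1 dpi, 0 to 2870 for mock against control at 3 dpi, 0 to 2735 and 0 to 2415 for the changes of particle against mock and mock against control, and 52 to 336 for control embryos, where control_3dpi B gave the lowest and control_3dpi C the highest count. The correlation of both times ran from −0.39 without particle_3dpi C to −0.11 without particle_3dpi A. For particle against control at 1 dpi erythroid genes ran from −0.632 (without control_1dpi B) to 0.0945 (without control_1dpi C), exocrine pancreas from −0.970 (without particle_1dpi A) to 2.45 (without control_1dpi A), intestinal epithelium from −0.219 to 2.15 (the same libraries), skeletal muscle from −0.00908 (without control_1dpi C) to 0.606 (without control_1dpi A) and ribosomal proteins from −0.315 (without control_1dpi B) to 0.115 (without control_1dpi C). At 3 dpi lens ran from −0.167 (without particle_3dpi A) to 0.538 (without control_3dpi B), exocrine pancreas from −0.763 to 3.42 and glucocorticoid response from −0.0168 to 0.487 (the same libraries), cholesterol biosynthesis from −0.266 (without control_3dpi C) to 0.0273 (without control_3dpi A) and heat shock and chaperones from −0.208 (without particle_3dpi C) to 0.0844 (without control_3dpi C). For mock against control at 1 dpi phototransduction ran from −0.194 (without control_1dpi C) to 0.553 (without control_1dpi B) and cell cycle from −0.413 (without control_1dpi B) to 0.0708 (without control_1dpi C), and at 3 dpi lens ran from −0.183 (without mock_3dpi A) to 0.776 (without mock_3dpi B). For control embryos lens ran from −0.485 (without control_3dpi B) to 0.136 (without control_3dpi C).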

Other observations

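In non-injected embryos the clock repressor per1a (ENSDARG00000056885, chromosome 10) rose from 3.07 ± 0.811 CPM at 1 dpi (3 dpf) to 74.3 ± 17.1 at 3 dpi (5 dpf), with n = 3 at each time, a log2 value of 4.61 (SE 0.27, adjusted p = 9.5e-07), and npas4a from 3.48 ± 1.13 to 95.6 ± 34.8, a value of 4.74 (SE 0.335, adjusted p = 6.33e-06), and both passed without any single library. The chitinase gene chia.2 rose by 6.29 (adjusted p = 0.0423), the phosphatase subunit gene ppp1r27b by 5.14 (adjusted p = 0.0248) and the drug metabolism gene cyp3a65 by 4.62 (adjusted p = 0.0323), while arntl2, a clock activator, fell by 1.74 (adjusted p = 0.0329), the pigment gene pmelb by 1.72 (adjusted p = 0.0151), casp3b by 1.61 (adjusted p = 0.0252), ppp1r14c by 1.46 (adjusted p = 0.0113) and SLC9B1 by 1.41 (adjusted p = 0.0161). In total 273 genes rose and 48 fell, and 52 were called without control_3dpi B, 70 without control_3dpi A, 88 without control_1dpi C, 113 without control_1dpi B and 173 without control_1dpi A, where chia.2 had adjusted p = 0.0863.

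The list of circadian clock and light response rose by 0.83 on average, with 16 members higher and 2 lower, and was the only list past camera with an estimated correlation as well (adjusted p = 0.00781 with an estimated correlation, A and B libraries 0.79). Age cannot be told apart here from any difference in time of day or light at sampling. Glucocorticoid response rose by 1.27 (5 members, 17 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation) and the NF-kB, AP-1 and JAK-STAT early response by 0.88 (6 members, adjusted p = 0.0502 with an estimated correlation). Other groups rose by the preset test, liver secreted proteins by 2.87 (1.90 without control_3dpi B), intestinal epithelium by 2.60, exocrine pancreas by 3.38 (1.07 without control_3dpi B) and lipoprotein and yolk lipid genes by 1.62, while the unfolded protein response and integrated stress response fell by 0.33, with 16 members lower when adjusted over the list alone. With an estimated correlation exocrine pancreas had adjusted p = 0.493 and the liver, intestinal, lipoprotein and unfolded protein response lists adjusted p = 0.316.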
